A study of Arabidopsis thaliana with 17 samples.

How the data were processed

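Poly(A) RNA of whole seedlings was sequenced as strand-specific dUTP libraries on a DNBSEQ instrument, from total RNA prepared with a Spectrum Plant kit. The 17 libraries cover Col-0, atdgcr14l-1 and OE-6 at 0 h and 24 h of 200 mM NaCl, with 2 libraries of Col-0 at 0 h and 3 in each other group. Groups were taken from the labels, which do not say whether replicates are separate plants or cultures, and each p-value therefore measures the spread between these samples.

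The deposited values are estimated counts (expected counts) per gene, 1 set per library, made by the authors and already whole numbers when deposited. Per the submitters' processing notes the tools were Bowtie2 2.4.5, StringTie 2.1.7 and DESeq2 2.11.40.7. Their order, the genome build, the strand used in counting and the sequence that reads were aligned to are not given in the sources used here. In the values, 2 is commoner (8767 times) than 1 (2703) or 3 (4203), as in counts derived from coverage. Each set holds 27655 genes, of which 2772 are 0 in every library and 210 belong to organelles. The values are per gene, so the comparisons of transcript usage that had been intended could not be run, nor could alternatives on transcripts, TPM or FPKM.

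Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr (21282 genes), libraries scaled by TMM, and a quasi-likelihood model with robust spread fitted to all 6 groups at once, with a common biological coefficient of variation of 19.5% and a median of 3.7 prior degrees of freedom. Contrasts were salt in each line, atdgcr14l-1 against Col-0, OE-6 against atdgcr14l-1 and OE-6 against Col-0 at each time, and the interactions of line and time. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM scaled by TMM, and fold changes use edgeR's default prior count. For a gene at 0 in every library of a group, the fold is a lower bound against a floor of 3 counts per library. With 1 to 3 counts in a group, the ratio carries a 95% counting interval, and no fold is given where both groups lie at or under the floor. In a simulation with known changes at this depth and these group sizes (tested on simulated data), 59.2% of 2-fold and 90% of 8-fold changes were recovered for the mutant against Col-0 at 0 h, and 62% and 98% at 24 h. False calls made up 6.8% and 5.8%.

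The 20 gene lists, written from general knowledge of Arabidopsis, cover ABA and osmotic stress, sodium and potassium transport, reactive oxygen scavenging, photosynthesis, SR splicing factors, other splicing factors, heat shock, jasmonate, salicylate, senescence, cell cycle, aquaporins, anthocyanin, iron, hypoxia, clock, and markers of root, guard cell, flower and seed storage. The seed storage list had fewer than 5 tested genes and was not tested. The other 19 were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with a correlation estimated for each list, and p was adjusted over the lists. Counts adjusted over the list alone adjust p among the members of that list. Genes with introns were compared with intronless genes, by the annotation of TAIR10.1, through the difference of median fold changes. The breakdown by exon number and the score per library were chosen after seeing the data. The score was compared between the mutant and all other libraries of the same time by a 2-sided exact permutation test.

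Named genes follow a rule: AtDGCR14L; the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between the libraries of the groups compared; and up to 3 members with the smallest p (4 for salt in Col-0) of each list that camera called or that had a called member. For the other comparisons the 3 largest rises and falls were taken. MRD1, HEI10 and MAF5 are followed through all groups because of their values. The lists, the rule, the contrasts and all but 1 of the alternatives were chosen before the data were examined.

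Alternatives were RLE scaling, no filter on low counts, a filter at 5 CPM (16383 genes), organelle genes left out, a model of only the groups compared, DESeq2 1.42.0, the replicate number as a block, each library left out in turn and the correlation estimated per list. Leaving out atdgcr14l-1 24 h replicate 3 and OE-6 24 h replicate 2 together was chosen after seeing the data. The overlap between genes changed in the mutant and moved the other way in OE-6 was set against independent lists and against 20 simulations of unchanged groups that shared the mutant libraries. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.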

Results

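RNA was sequenced from whole Arabidopsis thaliana seedlings of 3 lines, kept in hydroponic culture to an age of 14 days and sampled at 0 h or 24 h of 200 mM NaCl. The lines were Col-0, the wild-type accession, atdgcr14l-1, a mutant of AtDGCR14L, and OE-6, which is that mutant carrying AtDGCR14L behind the constitutive 35S promoter as a complementation line. The 17 libraries comprised 2 of Col-0 at 0 h and 3 of each of the other 5 groups. Each library held between 53058673 and 56464259 estimated counts, and 21282 of the 27655 annotated genes passed the filter on low counts. Levels are given as counts scaled by library size (CPM) ± SD and changes as log2 fold changes ± SE, with n as stated here. The labels do not say that the libraries of a group came from separate plants or cultures, so p-values measure the spread between these samples. No unsalted 24 h libraries were analysed here, and each salt comparison therefore also holds the passage of 24 h.

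The 0 h and 24 h libraries separated on the first principal component, which held 66.7% of the variance. At 24 h the mutant and OE-6 libraries lay further apart from one another than those of Col-0. Mean Spearman correlations within the group were 0.9926 to 0.9937 in Col-0, 0.9798 to 0.9868 in atdgcr14l-1 and 0.9736 to 0.9784 in OE-6. The libraries with the lowest correlation in these groups were OE-6 24 h replicate 2 (second component 92.8, against -6.1 and 7.4) and atdgcr14l-1 24 h replicate 3 (first component 115.5, against 90.5 and 76.1). Replicate 1 of OE-6 stood apart on the third component, which held 5.3% of the variance, at 0 h (-53.5, against -11.5 and -4.4) and at 24 h (-66.3, against 29.9 and -5.8).

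AtDGCR14L (AT3G07790, chromosome 3, 2487313 to 2489386 in TAIR10.1) is annotated with 1 exon and 1 transcript. At 0 h its level was 57.8 ± 2.96 CPM in Col-0 (59.9 and 55.71), 7.85 ± 0.95 in atdgcr14l-1 (6.76 to 8.52) and 47.46 ± 3.77 in OE-6 (43.25 to 50.51). At 24 h it was 75.07 ± 3.39 in Col-0 (72.22 to 78.82), 12.13 ± 0.90 in the mutant (11.27 to 13.06) and 74.78 ± 11.74 in OE-6 (67.61 to 88.32). The mutant thus held 13.6% of the Col-0 level at 0 h and 16.2% at 24 h, and OE-6 held 82.1% and 99.6%. The fall in the mutant was -2.88 ± 0.13 at 0 h (adjusted p = 1.98e-08) and -2.63 ± 0.12 at 24 h (adjusted p = 2.61e-08). The rise from the mutant to OE-6 was 2.60 ± 0.12 (adjusted p = 3.54e-08) and 2.62 ± 0.12 (adjusted p = 2.69e-08), and in each of these 4 comparisons AtDGCR14L had the smallest p of all genes. OE-6 did not differ from Col-0 past the threshold (-0.29 at 0 h, adjusted p = 1, and -0.01 at 24 h, adjusted p = 0.993). AtDGCR14L rose with salt by 0.63 ± 0.12 in the mutant (adjusted p = 0.000322), 0.66 ± 0.11 in OE-6 (adjusted p = 0.000184) and 0.38 ± 0.13 in Col-0 (adjusted p = 0.0234). The Col-0 call was lost without Col-0 0 h replicate 1, Col-0 0 h replicate 2 or Col-0 24 h replicate 2, with changes of 0.326 to 0.43 over the left-out libraries.

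**Figure D1:**
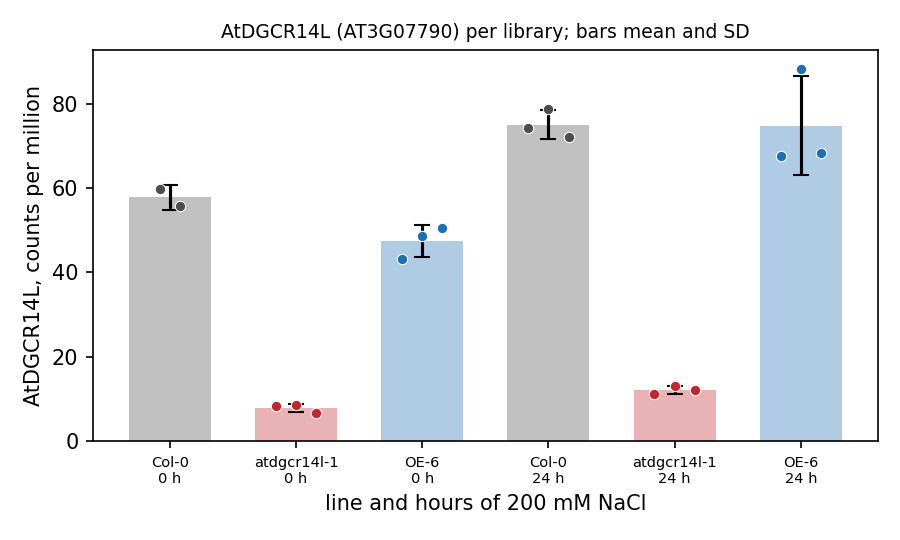
AtDGCR14L in CPM (y axis) in each line at 0 h and 24 h of NaCl (x axis), with points for libraries, bars for means and error bars for SD. The 6 atdgcr14l-1 libraries lie between 6.76 and 13.06, and every other library lies at 43.25 or above.

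The response of the wild type to salt was compared between Col-0 at 24 h (n = 3) and at 0 h (n = 2). The genes with the steepest rises were all but absent before salt. LTP4, a lipid transfer protein, went from 3 counts in all to 1500 ± 294 CPM, a ratio of 52800 (95% counting interval 18100 to 256000). Its paralog LTP3, named for its likeness to LTP4 after its values were seen, also rose, to 874 ± 94.5 CPM, and reads shared between such copies leave the level of each uncertain. Genes with no count in Col-0 at 0 h rose by at least 1890-fold (TPS04, a terpene synthase), 1370-fold (CSLA01), 509-fold (CYP94B3, which oxidises jasmonoyl-isoleucine), 414-fold (CYP82G1, which makes a homoterpene), 353-fold (BSMT1, a salicylate and benzoate methyltransferase), 277-fold (AT2G38240), 271-fold (AOX1D, an alternative oxidase), 255-fold (LEA7) and 215-fold (RAP2.6). These bounds were set against a floor of 3 counts per library and, like the interval, cover counting error only. The RAP2.6 call was lost without Col-0 0 h replicate 1 or 2 (highest adjusted p 0.0556).

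Among the genes that fell furthest, EXPA8, an expansin that loosens cell walls, fell by 6.41 ± 0.41 on the log2 scale (85.2-fold, adjusted p = 1.17e-07). GASA6, a gibberellin-regulated gene, fell by 5.11 ± 0.22 (adjusted p = 3.88e-09), and FLA9, an arabinogalactan protein, and CYP78A8 fell too (-4.1 ± 0.26 and -5.47 ± 0.29). MEE3 and RL3, small MYB-like proteins, changed by -5.18 ± 0.40 and -4.12 ± 0.30. BT2 (-3.83 ± 0.30), AT3G46490 (-4.35 ± 0.30) and AT3G55646 (-4.24 ± 0.23) also fell. MRD1 fell by 5.55 ± 0.69, from 37.4 ± 4.1 to 0.798 ± 1.05 CPM.

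Genes of the abscisic acid (ABA) and osmotic stress response rose almost throughout. Of 44 members 40 rose and none fell (41 and 0 adjusted over the list alone; median 2.72). KIN1, a cold- and ABA-induced protein, rose by 10.01 ± 0.53 to 692 ± 155 CPM. The dehydrin XERO2 rose by 6.75 ± 0.43, the caleosin RD20 by 5.94 ± 0.43 and ADC2, an arginine decarboxylase of polyamine synthesis, by 2.64 ± 0.17. Among 18 jasmonate genes 16 rose (16 adjusted over the list alone; median 2.96). They included the biosynthetic genes LOX2 (2.92 ± 0.24, to 3320 ± 512 CPM) and OPR3 (2.35 ± 0.20) and the repressors JAZ1 (4.67 ± 0.47) and JAZ10 (3.43 ± 0.36). Among 14 anthocyanin and flavonoid genes 12 rose (12 adjusted over the list alone; median 3.23). The MYB regulators PAP1 and PAP2 rose by 5.74 ± 0.37 and 6.14 ± 0.60 and the glycosyltransferases UF3GT and UGT75C1 by 5.16 ± 0.56 and 2.61 ± 0.24. Camera, limma's competitive gene set test, gave adjusted p = 2.28e-32 for ABA, 4.29e-11 for jasmonate and 1.01e-08 for anthocyanin, and adjusted p = 0.065, adjusted p = 0.18 and adjusted p = 0.18 with an estimated correlation.

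Nuclear-encoded photosynthesis genes fell in 44 of 46 cases (44 adjusted over the list alone; median -0.84). LHCA1, a photosystem I antenna protein, fell by 1.33 ± 0.18 (5600 ± 427 to 2230 ± 332 CPM). The photosystem II antenna genes LHCB2.3, LHCB1.4 and LHCB2.2, which have close copies and are uncertain one by one, changed by -2.37 ± 0.31, -2.05 ± 0.28 and -1.47 ± 0.20. Cell cycle genes fell in 16 of 18 cases (16 adjusted over the list alone; median -1.19), among them the replication helicase subunits MCM5 (37.8 ± 2.58 to 15.9 ± 1.27 CPM) and MCM2 (-1.19 ± 0.17), ribonucleotide reductase RNR1 (-1.0 ± 0.15) and the mitotic cyclin CYCB1;4 (-1.11 ± 0.18). Without Col-0 0 h replicate 2 the cell cycle count was 9. Camera gave adjusted p = 2.12e-14 for photosynthesis and 3.19e-06 for the cell cycle, and adjusted p = 0.37 and adjusted p = 0.479 with an estimated correlation.

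Senescence and chlorophyll breakdown genes rose in 9 and fell in 3 of 14 cases (10 and 3 adjusted over the list alone; median 3.02, or 2.43 with genes at 0 set to their bound). SAG13 rose by 8.01 ± 0.59, WRKY53 by 3.26 ± 0.39, and the chlorophyll breakdown genes PPH and NYE1 by 1.19 ± 0.12 and 0.95 ± 0.10. Scavengers of reactive oxygen rose in 11 and fell in 1 of 20 cases (12 and 1 adjusted over the list alone; median 0.91). DHAR1 rose by 2.95 ± 0.23, GSTU24 by 3.64 ± 0.50 and GPX6 by 1.23 ± 0.20, while the iron superoxide dismutase FSD2 fell (-1.09 ± 0.15). Heat shock genes rose in 9 and fell in 1 of 15 cases (9 and 1 adjusted over the list alone; median 3.38, or 2.83 with genes at 0 set to their bound). HSP17.4 rose by 8.20 ± 0.82, HSP18.2 by 3.46 ± 0.66 and HSP21 at least 14.5-fold, while the regulator HSFA7A fell by 2.82 ± 0.39. Salicylate and immunity genes rose in 10 of 18 cases (10 adjusted over the list alone; median 1.86), including PR2 (6.62 ± 1.06), PAD3 of camalexin synthesis (5.91 ± 1.24), CBP60G (2.35 ± 0.38) and EDS5 (1.93 ± 0.36). Camera gave adjusted p = 0.000343, 0.00982, 0.0272 and 0.0139 in this order, and adjusted p = 0.18, adjusted p = 0.279, adjusted p = 0.597 and adjusted p = 0.646 with an estimated correlation. Heat shock rises numbered 5 without Col-0 0 h replicate 1, salicylate rises 6 without Col-0 0 h replicate 2, and senescence falls 1 without Col-0 0 h replicate 1.

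The other lists had members going both ways or few members past the threshold, and camera called none of them. Of 20 genes of sodium and potassium transport 5 rose and 6 fell (5 and 6 adjusted over the list alone; median 0.01 but mean -0.119; camera adjusted p = 0.627). HKT1, the sodium transporter that unloads the xylem, fell by 4.03 ± 0.39. The calcium sensor CBL10 (-0.82 ± 0.11) and the proton pump AVP1 (-0.56 ± 0.10) fell, while the exchanger NHX6 rose by 0.89 ± 0.10. Without Col-0 0 h replicate 2 the number that rose was 2. Of 20 SR splicing factors 5 rose and 6 fell (5 and 6 adjusted over the list alone; median 0.008 but mean -0.032; camera adjusted p = 0.707). SR45A rose by 0.62 ± 0.09 and RS31A by 0.50 ± 0.11, with RS41 at -0.51 ± 0.08 and RSZ22A at -0.54 ± 0.11. The SR counts were 2 and 3 without Col-0 0 h replicate 1 and 3 and 4 without replicate 2. Of 29 other splicing factors 9 fell (8 adjusted over the list alone; camera adjusted p = 0.0761), among them GRP8 (-0.96 ± 0.16), CLO (-0.65 ± 0.11), RBM25 (-0.62 ± 0.11) and U2AF65A (-0.50 ± 0.10). Aquaporins rose in 4 and fell in 9 of 18 cases (4 and 9 adjusted over the list alone; camera adjusted p = 0.0761). TIP2;1, PIP1;3 and TIP2;2 changed by -2.41 ± 0.32, -1.18 ± 0.12 and -0.83 ± 0.11, while PIP2;3 rose by 1.39 ± 0.19.

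Of 10 hypoxia genes 3 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.555), with ADH1 up by 2.84 ± 0.51, SUS1 by 2.41 ± 0.31, PDC1 by 1.63 ± 0.50 and LBD41 down (-0.75 ± 0.24). No hypoxia gene fell past the threshold without Col-0 0 h replicate 1 or 2. PDC1 was lost without either of these (highest adjusted p 0.119), and LBD41 without either or Col-0 24 h replicate 2 (0.112). Of 13 clock genes 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.323). The falls included PRR5 (-1.18 ± 0.13), PRR7 (-0.88 ± 0.16) and GI (-0.66 ± 0.17). ELF4 rose by 0.80 ± 0.20, lost without Col-0 0 h replicate 2 (adjusted p = 0.0593). Of 16 genes of iron deficiency and storage FRO2 rose (1.63 ± 0.51) and BHLH100 fell at least 23.8-fold (none adjusted over the list alone; median 0.027 but mean -0.742; camera adjusted p = 0.921). FRO2 was lost without Col-0 0 h replicate 2 (adjusted p = 0.16), and BHLH100 without that library or any 1 of the Col-0 24 h libraries (highest adjusted p 1). No iron gene fell past the threshold without atdgcr14l-1 0 h replicates 2 or 3 or OE-6 0 h replicates 1 or 3 either, and without atdgcr14l-1 0 h replicate 1 there were 2 rises and 2 falls. Of the marker lists for cell types and organs, 1 of 5 tested root genes fell (PRP3 -2.07 ± 0.70, camera adjusted p = 0.555), 1 of 5 guard cell genes fell (KAT1 -0.69 ± 0.19, camera adjusted p = 0.561). Of 11 floral genes 1 rose (SOC1 0.35 ± 0.13, camera adjusted p = 0.816). Adjusted over the list alone these counts were 0, 1 and 0. PRP3 was lost without Col-0 0 h replicate 1 or 2 or Col-0 24 h replicate 1 (highest adjusted p 0.134), SOC1 without the same libraries (0.198) and KAT1 without Col-0 0 h replicate 1 (0.106).

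In all, 9953 genes (46.8% of those tested) changed with salt in Col-0, 5405 up and 4548 down, and 2424 and 1464 of these changed at least 2-fold (edgeR quasi-likelihood test, adjusted p under 0.05). With 2 libraries at 0 h the self-test on simulated counts recovered 72% of 2-fold changes and 91.8% of 8-fold changes in this comparison.

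The same contrast in atdgcr14l-1 and OE-6 (n = 3 at each time) asked which genes responded to salt without and with the transgene. LTP4 rose in the mutant to 1310 ± 389 CPM (ratio 70800, 95% counting interval 24200 to 343000), RAP2.6 by at least 2410-fold and the sucrose transporter SUC7 by at least 1060-fold. In OE-6 the bounds were 521-fold for RAP2.6, 497-fold for AOX1D and 484-fold for SUC7. EXPA8 changed by -6.43 ± 0.41 in the mutant and -6.40 ± 0.40 in OE-6. Other steep falls were AT3G21460 (-6.70 ± 0.58) and AT3G62950 (-6.19 ± 0.52) in the mutant and CYP78A8 (-6.39 ± 0.30) and MEE3 (-5.81 ± 0.41) in OE-6. ABA genes rose in 43 of 44 cases in each line (43 adjusted over the list alone), jasmonate genes in 16 of 18 (16), anthocyanin genes in 13 of 14 (13), and photosynthesis genes fell in 44 of 46 (44) and cell cycle genes in 17 of 18 (17). Camera called these 5 lists in both lines at an adjusted p of at most 2.93e-07, and none with an estimated correlation, where the smallest were adjusted p = 0.0736 in the mutant and adjusted p = 0.0695 in OE-6. It also called reactive oxygen scavenging (15 up and 1 down in the mutant, 14 and 3 in OE-6; 15 and 2, and 14 and 3 adjusted over the list alone) at adjusted p = 0.00192 and 0.0102. Senescence (10 up and 3 down in both lines, and the same counts adjusted over the list alone) was called at 0.000681 and 4.05e-05. Heat shock genes rose in 13 and fell in 1 of 15 cases in the mutant (14 and 1 adjusted over the list alone; adjusted p = 0.011) and rose in 10 and fell in 1 in OE-6 (10 and 1 adjusted over the list alone; adjusted p = 0.0592). Salicylate genes rose in 8 of 18 cases in the mutant (8 adjusted over the list alone; adjusted p = 0.138) and in 11 in OE-6 (11 adjusted over the list alone; adjusted p = 0.0116). With an estimated correlation the smallest of the 6 calls was adjusted p = 0.157. In all, 12336 genes changed in atdgcr14l-1 (6659 up, 5677 down) and 11759 in OE-6 (6288 up, 5471 down). Of 8880 genes called in both Col-0 and the mutant 8879 went the same way, and of 8821 called in both Col-0 and OE-6 8819 did. Independent lists of these sizes would share 1690 higher and 1210 lower genes, and 1600 and 1170.

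The untreated mutant was compared with untreated Col-0 (n = 3 against 2) for the effect of reduced AtDGCR14L before salt. A few genes of the ABA and osmotic stress list were lower in the mutant. COR15A, a chloroplast cryoprotective protein, was at 3.93 ± 2.07 against 43.4 ± 1.36 CPM (-3.47 ± 0.48, adjusted p = 0.0018) and its tandem copy COR15B at 17.3 ± 8.34 against 115 ± 2.36 (-2.73 ± 0.41, adjusted p = 0.00327), with reads of the copies possibly shared. KIN2 was at 122 ± 22.3 against 390 ± 32.5 (-1.68 ± 0.19, adjusted p = 0.000302), and RD29A was lower by -1.83 ± 0.36 (adjusted p = 0.0164). Of 44 ABA and osmotic stress genes these 4 were lower and none higher (5 and 0 adjusted over the list alone; median -0.37). Camera gave adjusted p = 3.28e-08, the only list called, and adjusted p = 0.993 with an estimated correlation. RD29A was lost without Col-0 0 h replicate 1 or atdgcr14l-1 0 h replicates 1 or 3 (highest adjusted p 0.341), and RD29A and COR15B were lost in a model of the 2 groups compared alone, which called 12 ABA genes.

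MAF5, a relative of the floral repressor FLC, was 10.4-fold higher in the mutant (29.8 ± 3.63 against 2.87 ± 1.37 CPM, adjusted p = 1.9e-05). QQS, an orphan gene that affects starch content, was 5.88-fold higher (2.56 ± 0.31), and TPPJ, a trehalose phosphate phosphatase that lies near MAF5 on chromosome 5, 3.10-fold (1.63 ± 0.21). Smaller rises were seen for the helicase gene RecQl3 (1.49 ± 0.12, adjusted p = 2.84e-05), the actin-related ARP2 (1.42 ± 0.10, adjusted p = 6.41e-06), QWRF3 (1.42 ± 0.17), EMB1895 (1.39 ± 0.18), MEE13 (1.32 ± 0.12), CSLB03 (1.45 ± 0.32) and AT4G19430 (1.41 ± 0.22). Lower in the mutant were also AT3G59330 (-1.66 ± 0.22), the signal recognition particle RNA AT7SL-1 (-1.41 ± 0.27), UGT84A3 (-1.35 ± 0.16), AT5G11330 (-1.30 ± 0.16) and the poly(A) polymerase PAPS2 (-1.20 ± 0.16). CSLB03 and AT7SL-1 were each lost without Col-0 0 h replicate 1 or 2 or atdgcr14l-1 0 h replicate 2 or 3 (highest adjusted p 0.28 and 0.133), and AT4G19430 without either Col-0 library (0.0672).

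Of 13 clock genes 1 was higher and 3 lower (3 and 4 adjusted over the list alone; median -0.18 but mean 0.295; camera adjusted p = 0.963). The morning-phased activator RVE8 was 7.82-fold higher (2.97 ± 0.39, adjusted p = 0.000868), and ELF4 (-1.05 ± 0.19) and FKF1 (-0.53 ± 0.11) were lower. No clock gene was lower past the threshold without Col-0 0 h replicate 1, Col-0 0 h replicate 2 or atdgcr14l-1 0 h replicate 3, and 1 was without replicate 1 of the mutant. ELF4 reached an adjusted p of 0.15 and FKF1 of 0.248 without Col-0 0 h replicate 1. In sodium and potassium transport SOS1, the plasma membrane sodium exporter, was higher (0.79 ± 0.15) and the vacuolar exchanger NHX2 lower (-0.83 ± 0.19; 2 and 1 adjusted over the list alone). Among splicing factors SR30 was lower (-0.39 ± 0.08; 1 adjusted over the list alone), and in chlorophyll breakdown NOL was lower (-0.60 ± 0.11; 1 adjusted over the list alone). SOS1 and NOL were lost without either Col-0 library (highest adjusted p 0.142 and 0.141), and NHX2 and SR30 without any of the 5 libraries (0.271 and 0.247). No gene of this transport list was lower without OE-6 0 h replicate 2. The remaining 14 lists had no member past the threshold in edgeR, with 18 of their 243 genes at an unadjusted p under 0.05 and 3 called by DESeq2.

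In all, 431 genes differed between the lines at 0 h, 309 higher and 122 lower in the mutant, and 50 and 36 of them at least 2-fold. The count was 90 and 95 without Col-0 0 h replicates 1 and 2, and 214, 212 and 182 without replicates 1, 2 and 3 of the mutant. It was 2330 in a model of these 5 libraries alone and 917 with DESeq2, which called all 431.

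OE-6 was compared with the mutant at 0 h (n = 3 each) for genes that the transgene moved. Of the ABA and osmotic stress genes COR15A was higher in OE-6 by 3.28 ± 0.45 (38.2 ± 19 against 3.93 ± 2.07 CPM, adjusted p = 0.000954), COR15B by 2.67 ± 0.39 (110 ± 24.1 CPM) and KIN2 by 1.62 ± 0.18 (375 ± 25.8 CPM, adjusted p = 0.000129). RD29A (1.59 ± 0.33) was higher too, as was DREB1A (1.91 ± 0.26), a regulator of cold-responsive genes that is not in this list. In the ABA list 6 of 44 were higher and none lower (14 and 0 adjusted over the list alone; median 0.42; camera adjusted p = 9.44e-12, and adjusted p = 0.593 with an estimated correlation). SOS1 (-0.96 ± 0.13, adjusted p = 0.000548) and its kinase SOS2 (-0.78 ± 0.13) were lower and NHX2 higher (0.95 ± 0.18; 1 higher and 2 lower adjusted over the list alone). Clock genes were higher in 4 and lower in 2 of 13 cases (5 and 4 adjusted over the list alone; median 0.16 but mean -0.36), with RVE8 at -3.02 ± 0.33, LHY at -1.89 ± 0.34 and ELF4 at 1.14 ± 0.18. The number higher was 2 without any of the 6 libraries in turn.

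Floral markers were higher in OE-6 in 2 of 11 cases (3 adjusted over the list alone; median 1.57; camera adjusted p = 1.71e-05, and adjusted p = 0.593 with an estimated correlation). These were SOC1 (0.53 ± 0.12) and SEP2 (3.85 ± 0.98, 4.13 ± 2.12 CPM in OE-6). SOC1 was lost without atdgcr14l-1 0 h replicate 1 or 2 or OE-6 0 h replicate 1 or 2 (highest adjusted p 0.0862) and SEP2 without any of the 6 libraries (0.161). The floral count was 1 without either Col-0 0 h library. Jasmonate genes were higher in 2 of 18 cases (5 adjusted over the list alone; median 0.28; camera adjusted p = 0.00688, and adjusted p = 0.971 with an estimated correlation), with LOX2 at 0.85 ± 0.19 and the storage protein VSP1 at 2.92 ± 0.67. LOX2 was lost without atdgcr14l-1 0 h replicates 1 or 3 or OE-6 0 h replicates 1 or 3 (0.102), and VSP1 without any mutant library or OE-6 0 h replicate 1 (0.116). MRD1 was 176-fold lower in OE-6 (0.196 ± 0.148 against 34.9 ± 2.23 CPM, -7.46 ± 0.79, adjusted p = 0.000177). HEI10, a meiotic crossover factor, was 4.81-fold lower (-2.27 ± 0.20). MRD1 (chromosome 1, 19963047 to 19964712) and HEI10 (19963267 to 19966952) overlap on opposite strands, and the strand used in counting is not given in the sources used here, so the counts of HEI10 may hold reads of the MRD1 locus.

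QQS (-2.51 ± 0.27), RecQl3 (-1.53 ± 0.11, adjusted p = 3.55e-06), EMB1895 (-1.49 ± 0.16) and AT4G19430 (-1.43 ± 0.19) were lower in OE-6 than in the mutant. So were GASA1 (-1.74 ± 0.24), NDA1 (-1.62 ± 0.34), HTA4 (-1.62 ± 0.33) and AT1G62510 (-1.61 ± 0.33). AT3G59330 (1.47 ± 0.20), AT7SL-1 (1.47 ± 0.25) and AT1G51090 (1.55 ± 0.26) were higher. Single members of 3 more lists passed the threshold: the catalase CAT2 (-1.22 ± 0.24), SR30 (0.34 ± 0.07) and NOL (0.56 ± 0.10). Adjusted over the list alone each of these lists also had 1. The remaining 11 lists had none in edgeR, with 11 of 194 genes at an unadjusted p under 0.05 and 2 called by DESeq2. SR30 was lost without any library but OE-6 0 h replicate 3 (0.0742), CAT2 without atdgcr14l-1 0 h replicate 1 (0.0502). RD29A was lost without atdgcr14l-1 0 h replicates 1 or 3 or OE-6 0 h replicate 2 (0.0761) and AT1G62510 without OE-6 0 h replicate 1 (0.0645). NDA1 was lost without atdgcr14l-1 0 h replicate 1 or OE-6 0 h replicates 2 or 3 (0.0734) and HTA4 without atdgcr14l-1 0 h replicate 2 or OE-6 0 h replicates 1 or 3 (0.0609).

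In all, 972 genes differed, 314 higher and 658 lower in OE-6, with 70 and 86 at least 2-fold. Left-out libraries gave 492, 501 and 520 genes for replicates 1, 2 and 3 of the mutant and 462, 642 and 530 for those of OE-6, the groups compared alone gave 3185 and DESeq2 1596. Of the 431 genes that differed in the mutant 398 moved the other way in OE-6 past the threshold, 295 of them higher and 103 lower in the mutant. Independent lists would share 9.55 and 1.80. Both comparisons use the same mutant libraries, and 20 simulations of unchanged groups around them gave 0 such genes by the same edgeR test. That sets no reference for the 398, as the simulated comparisons called at most 2 and 0 genes. With simulated libraries the fold changes correlated at -0.454 on average across genes, which are not independent replicates. The observed correlation, -0.402, was weaker. The observed covariance was -0.184 against -0.109. The 3 mutant libraries cannot be split, so part of the overlap may come from them. The number of reversed genes was 84 and 91 without Col-0 0 h replicates 1 and 2, 196, 193 and 169 without replicates 1, 2 and 3 of the mutant, and 790 with DESeq2.

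At 24 h of salt the mutant was compared with Col-0 (n = 3 each). Anthocyanin and flavonoid genes were higher in the mutant in 11 of 14 cases and lower in none (12 and 0 adjusted over the list alone; median 1.33). TT8, a bHLH regulator of the pathway, was at 10.6 ± 2.16 against 2.26 ± 0.167 CPM (2.22 ± 0.43, adjusted p = 0.0053). The glucosyltransferase UGT75C1 was at 55.9 ± 9.97 against 27.4 ± 3.79 (1.03 ± 0.19, adjusted p = 0.00446) and chalcone isomerase TT5 was higher by 0.73 ± 0.15. Jasmonate genes were higher in 7 of 18 cases and lower in none (14 and 0 adjusted over the list alone; median 0.99), with OPR3 at 365 ± 38.5 against 185 ± 36.9 CPM (0.98 ± 0.17), LOX3 at 0.87 ± 0.17 and JAZ10 at 1.31 ± 0.27. Camera called these 2 lists, at adjusted p = 1.8e-09 and 6.77e-08, and adjusted p = 0.408 for each with an estimated correlation. The anthocyanin count was 6, 4 and 6 without Col-0 24 h replicates 1, 2 and 3, and 11 without atdgcr14l-1 24 h replicate 3 and OE-6 24 h replicate 2, an alternative chosen after seeing the data, under which 6 jasmonate genes were higher.

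ABA and osmotic stress genes went both ways, with 7 higher and 4 lower of 44 (10 and 6 adjusted over the list alone; camera adjusted p = 0.509). GOLS1, a galactinol synthase of raffinose synthesis, was at 172 ± 33.6 against 40.4 ± 10.3 CPM (2.09 ± 0.36) and ADC2 was higher by 0.82 ± 0.14, while KIN2 was at 1210 ± 145 against 2290 ± 182 CPM (-0.93 ± 0.18). COR15B was at 74.8 ± 22.2 against 285 ± 68.5 CPM (-1.93 ± 0.37) and DREB1A at 5.17 ± 0.442 against 16 ± 1.81 (-1.63 ± 0.25, adjusted p = 0.00144). The ABA counts were 4 and 15 without the 2 libraries that stood apart, and without single libraries 3 and 3 (Col-0 replicate 1), 2 and 2 (Col-0 replicates 2 and 3 each), 8 and 2 (mutant replicate 1), 10 and 2 (mutant replicate 2) and 2 and 3 (mutant replicate 3). SOS1 was again higher in the mutant (37 ± 6.49 against 20.3 ± 2.24 CPM, 0.87 ± 0.13, adjusted p = 0.000982; 1 adjusted over the list alone). Clock genes were higher in 2 and lower in 2 of 13 cases (4 and 4 adjusted over the list alone; median -0.002 but mean 0.301), with RVE8 at 2.03 ± 0.31, ELF4 at -0.93 ± 0.18 and FKF1 at -0.52 ± 0.10. Without mutant replicates 1 or 2 the number of clock genes higher was 4, and without mutant replicate 2 the number lower was 4.

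Of 20 SR splicing factors 4 were lower in the mutant and none higher (4 and 1 adjusted over the list alone), by small amounts (SR34 -0.33 ± 0.08, RS31 -0.36 ± 0.09 and RS40 -0.29 ± 0.08). Of 29 other splicing factors 2 were lower (1 adjusted over the list alone; U2AF35B -0.56 ± 0.12, adjusted p = 0.0106, and MAC3B -0.31 ± 0.10). Leaving out 1 library gave 1 to 4 SR genes: 1 without Col-0 24 h replicate 2 or atdgcr14l-1 24 h replicate 3, and 2 without Col-0 24 h replicate 3 or atdgcr14l-1 24 h replicate 1. The other splicing factors numbered 4 without Col-0 24 h replicate 1 and 1 without Col-0 24 h replicates 2 or 3 or atdgcr14l-1 24 h replicates 1 or 3. In a model of the groups compared alone, no SR gene passed. MAC3B and RS40 were lost without Col-0 24 h replicates 2 or 3 or atdgcr14l-1 24 h replicates 1 or 3 (highest adjusted p 0.171 and 0.0945) and RS31 without any Col-0 library or mutant replicate 3 (0.0799). Aquaporins were higher in 3 of 18 cases (3 adjusted over the list alone; PIP2;3 0.92 ± 0.16, PIP2;1 0.58 ± 0.14 and PIP1;1 0.65 ± 0.18) and only 1 was without Col-0 24 h replicate 2 or atdgcr14l-1 24 h replicate 3, against 7 without OE-6 24 h replicate 2. Oxidative stress genes were higher in 2 of 20 cases (1 adjusted over the list alone; CAT2 0.92 ± 0.24 and GSTU25 2.68 ± 0.83). The count was 0 without Col-0 replicates 1 or 2 or mutant replicate 3, 1 without Col-0 replicate 3, and 5 and 4 without mutant replicate 2 and OE-6 replicate 3. LHCB1.1 (1.22 ± 0.26) was the only photosynthesis gene higher, HSP17.6II (3.51 ± 0.87) the only heat shock gene, and KAT1 (0.64 ± 0.17) the only guard cell gene. Adjusted over the list alone 1, 9 and 1 genes of these lists were higher. In chlorophyll breakdown NOL was lower (-0.69 ± 0.10) and PPH higher (0.42 ± 0.10; 1 and 1 adjusted over the list alone). The remaining 6 lists, among them root and floral markers, had no member past the threshold in edgeR, with 7 of 78 genes at an unadjusted p under 0.05 and 3 called by DESeq2.

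Genes with large rises included MRD1 (45.9 ± 2.99 in the mutant against 0.798 ± 1.05 CPM in Col-0, 5.85 ± 0.67, adjusted p = 0.000275), MAF5 (32.3 ± 5.68 against 1.49 ± 0.143, 4.43 ± 0.24, adjusted p = 1.62e-07) and QQS (8.46-fold, 3.08 ± 0.28). Other large rises rested on wide replicates, the largest of them AT5G46610 (5.96 ± 1.68, adjusted p = 0.0447). The means in the mutant were 31.4 ± 51.6 CPM for AT5G46610, 31.3 ± 34.7 for MIOX2, 276 ± 254 for the nitrate transporter NRT1.8, 20.3 ± 16.7 for the asparagine synthetase ASN1, 17.9 ± 24.3 for HSP17.6II, 127 ± 118 for AT2G38240 and 9.85 ± 9.76 for AT2G47550. Apart from MIOX2 these were lost without atdgcr14l-1 24 h replicate 3, which stands apart, and also without Col-0 24 h replicate 2 (highest adjusted p 0.333, for AT5G46610). Col-0 24 h replicate 1 also ended the calls of AT5G46610, HSP17.6II, ASN1 and AT2G47550, and replicate 3 those of AT5G46610, HSP17.6II, NRT1.8, AT2G38240 and AT2G47550. Lower in the mutant were AT4G16880 (-1.69 ± 0.30), AT1G70640 (-1.57 ± 0.38), AT5G11330 (-1.53 ± 0.15), CIPK25 (-1.49 ± 0.38), AT7SL-1 (-1.49 ± 0.24), GolS3 (-1.48 ± 0.39) and AT5G66790 (-1.46 ± 0.25). AT1G70640 was lost without atdgcr14l-1 24 h replicate 1 (0.0546), CIPK25 without mutant replicates 1 or 2 or Col-0 24 h replicates 2 or 3 (0.0689) and GolS3 without any library but mutant replicate 3 (0.0683).

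In all, 2633 genes differed, 1640 higher and 993 lower in the mutant, with 356 and 107 at least 2-fold. The count was 1303, 1109 and 1632 without Col-0 24 h replicates 1, 2 and 3, 1358 without atdgcr14l-1 24 h replicate 3 and 827 with the groups compared alone. Of the 337 genes called at both times 335 went the same way, 264 higher and 71 lower, where independent lists would share 23.8 and 5.69. Of the 47 named genes 18 lost their call with at least 1 library left out. PIP1;1, GSTU25, CAT2, PPH, PIP2;1 and KAT1 were among them, each without mutant replicate 3 (highest adjusted p over left-out libraries 0.116, 0.222, 0.117, 0.0831 and 0.0849 for the first 5). Col-0 24 h replicates 1, 2 or 3 ended the calls of PIP1;1 and GSTU25, replicates 1 or 2 that of CAT2, replicates 2 or 3 that of PPH, replicate 2 that of PIP2;1, and replicates 1 or 3 and mutant replicate 1 that of KAT1. With the groups compared alone 18 lost it, MIOX2, AT4G16880, LHCB1.1 and SR34 among them.

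OE-6 and the mutant were compared at 24 h (n = 3 each), where the 2 groups vary most. Anthocyanin genes were lower in OE-6 in 11 of 14 cases and higher in none (12 and 0 adjusted over the list alone; median -1.34). UGT75C1 differed by -1.16 ± 0.19 (24.9 ± 7.75 against 55.9 ± 9.97 CPM, adjusted p = 0.00251), LDOX by -1.90 ± 0.37 and TT8 by -2.03 ± 0.42. Jasmonate genes were lower in 4 of 18 cases (7 adjusted over the list alone; median -0.75), namely OPR3 (-0.94 ± 0.17), AOS (-0.90 ± 0.18) and JAZ10 (-1.39 ± 0.27) among others. Heat shock genes were lower in 4 of 15 cases (10 adjusted over the list alone; median -1.15), including BIP1 (-0.52 ± 0.14), HSP17.6II (-3.87 ± 0.88) and HSP17.6A (-3.63 ± 1.00). Camera gave adjusted p = 6.61e-09, 0.000293 and 0.00881, and adjusted p = 0.518, adjusted p = 0.618 and adjusted p = 0.618 with an estimated correlation. Without atdgcr14l-1 24 h replicate 1 the anthocyanin count was 4. Without the 2 libraries that stood apart the counts were 10, 3 and 0, and in a model of these 6 libraries alone no gene of any list passed. The heat shock count was 0 without mutant replicate 3 or OE-6 replicate 2, 1 without OE-6 replicate 3, 2 without mutant replicate 1 and 10 without mutant replicate 2.

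ABA genes were higher in OE-6 in 6 and lower in 2 of 44 cases (8 and 3 adjusted over the list alone; median 0.29; camera adjusted p = 0.0364, and adjusted p = 0.867 with an estimated correlation). KIN2 was at 1.01 ± 0.18, GOLS2 at 1.55 ± 0.35 and ADC2 at -0.79 ± 0.14. COR15B (1.64 ± 0.37) and DREB1A (1.65 ± 0.25, 16.2 ± 7.28 against 5.17 ± 0.442 CPM) were also higher, and COR15B was lost without mutant replicate 3 or OE-6 replicate 2 (highest adjusted p 0.0595). The ABA counts were 3 and 1 without OE-6 replicate 2, 10 and 5 without OE-6 replicate 1, and 3 were higher without mutant replicate 1. Falls numbered 4 without mutant replicate 2 and 1 without OE-6 replicate 3. SOS1 was lower (-0.76 ± 0.13, adjusted p = 0.00263) and NHX2 higher (0.57 ± 0.17; 1 lower adjusted over the list alone). Aquaporins were lower in 2 of 18 cases (7 lower and 1 higher adjusted over the list alone; PIP2;3 -1.03 ± 0.16 and PIP2;1 -0.54 ± 0.14; camera adjusted p = 0.0289, and adjusted p = 0.618 with an estimated correlation). The count was 1 without mutant replicate 3 and 7 without OE-6 replicate 1. Among 46 photosynthesis genes LHCB1.4 was higher (1.55 ± 0.26; 1 adjusted over the list alone; camera adjusted p = 0.0452, and adjusted p = 0.883 with an estimated correlation).

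Floral markers were higher in OE-6 in 4 of 11 cases (8 adjusted over the list alone; median 1.93; camera adjusted p = 0.000602, and adjusted p = 0.618 with an estimated correlation). SOC1 was at 67.1 ± 10 against 40.3 ± 2.72 CPM (0.73 ± 0.12, adjusted p = 0.00217), FUL was higher by 1.12 ± 0.29 and SEP3 by 3.07 ± 0.70 with 8.24 ± 9.67 CPM in OE-6. The floral count was 1 without mutant replicate 3, 2 without mutant replicate 1 or OE-6 replicate 1 and 7 without OE-6 replicate 2, the library with the lowest correlation to its group. SEP3 was lost without mutant replicate 3 (0.0611), and FUL without mutant replicates 1 or 3 or OE-6 replicate 1 (0.0823). Of the 5 root markers tested, out of 14 listed, NRT2.1 was higher (2.18 ± 0.64) and PHO1 lower (-0.91 ± 0.22). The counts of PRP3, also called lower, lie at or under the floor in both groups, so no fold is given. Adjusted over the list alone 1 root marker was higher and 2 lower, and no root marker was lower without mutant replicate 3 or OE-6 replicate 2. Clock genes were higher in 4 and lower in 2 of 13 cases (5 and 2 adjusted over the list alone), with FKF1 at 0.66 ± 0.10, ELF4 at 1.11 ± 0.18 and RVE8 at -1.95 ± 0.31. The number of clock genes higher was 2 without mutant replicates 1 or 3 or OE-6 replicates 2 or 3, and the number lower 1 without the last 3 of these. Splicing factors past the threshold were RS31 (0.36 ± 0.09), RSZ22A (-0.38 ± 0.10) and U1-70K (0.26 ± 0.08), with 3 SR genes higher, 2 lower and no other splicing factor adjusted over the list alone. No SR gene passed without mutant replicate 3, and none was higher without OE-6 replicate 3 or lower without OE-6 replicate 2. NOL was higher (0.60 ± 0.10; 1 adjusted over the list alone). The remaining 6 lists had none in edgeR, with 12 of 87 genes at an unadjusted p under 0.05 and 5 called by DESeq2.

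MRD1 was 310-fold lower in OE-6 (0.147 ± 0.0687 against 45.9 ± 2.99 CPM, adjusted p = 0.000178), and HEI10, with the overlap noted for 0 h, 5.94-fold lower (-2.57 ± 0.20, adjusted p = 1.47e-05). AT1G78460 was higher (1.83 ± 0.21, adjusted p = 0.000334), as were AT5G11330 (1.59 ± 0.15), AT5G66790 (1.62 ± 0.25), AT4G16880 (1.59 ± 0.30), AT5G35480 (1.77 ± 0.34), ATA20 (1.94 ± 0.40) and GolS3 (1.58 ± 0.39). LRX2, a root hair cell wall protein (-2.63 ± 0.53), MIOX2 (-4.59 ± 0.83), SQP2 (-3.93 ± 1.09), ASN1 (-2.66 ± 0.67), AT2G38240 (-2.59 ± 0.75), BAM5 (-2.57 ± 0.62) and NRT1.8 (-2.48 ± 0.71) were lower. SQP2, HSP17.6II, ASN1, AT2G38240 and NRT1.8 were each lost without mutant replicate 3, OE-6 replicate 2 or OE-6 replicate 3 (highest adjusted p 0.2, 0.0764, 0.0999, 0.215 and 0.208), and BAM5 without either of the OE-6 libraries (0.0614). RS31 and PIP2;1 were lost without mutant replicate 3 or OE-6 replicate 3 (0.0776 and 0.0977), and RSZ22A and PHO1 without mutant replicate 3 or OE-6 replicate 2 (0.103 and 0.0676). GolS3 was lost without mutant replicate 1 or OE-6 replicate 2 (0.0761) and NHX2 without mutant replicates 1 or 3 or OE-6 replicate 2 (0.187). U1-70K and BIP1 were lost without mutant replicates 1 or 3 or OE-6 replicates 2 or 3 (0.103 and 0.111) and HSP17.6A without mutant replicate 3 or any OE-6 library (0.414). NRT2.1 was lost without any library but OE-6 replicate 2 (0.0893) and PRP3 without any but mutant replicate 2 (0.131). Of the 49 named genes 20 lost their call with at least 1 library left out and 21 without both libraries that stood apart.

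In all, 2546 genes differed, 1100 higher and 1446 lower in OE-6, with 193 and 243 at least 2-fold. Only 7 genes passed with spread, filter and scaling from these 6 libraries alone. They included AtDGCR14L, AT1G78460, MRD1 and HEI10, the only 4 of 49 named genes to keep their call. The 2546 rest on a spread shared with groups that vary less. The count was 1452 without mutant replicate 3, 3851 without its replicate 2, 4140 and 1514 without OE-6 replicates 1 and 2, 1155 without both libraries that stood apart and 3926 with DESeq2. Of the 2633 genes that differed in the mutant 1553 moved back in OE-6, 972 higher and 581 lower in the mutant. Independent lists would share 111 and 51.3. The 20 simulations gave 0, which sets no reference for the 1553, as each simulated comparison called at most 1 gene. The correlation across genes was -0.586 against -0.504 in the simulations and the covariance -0.271 against -0.098. The simulated covariance was no larger than at 0 h, though the mutant varied more at 24 h. The excess may come from the shared libraries, as may part of the overlap. The reversed genes numbered 978 and 828 without Col-0 24 h replicates 1 and 2, 2513 and 861 without atdgcr14l-1 24 h replicates 2 and 3, 909 without both libraries that stood apart and 2424 with DESeq2.

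**Figure D2:**
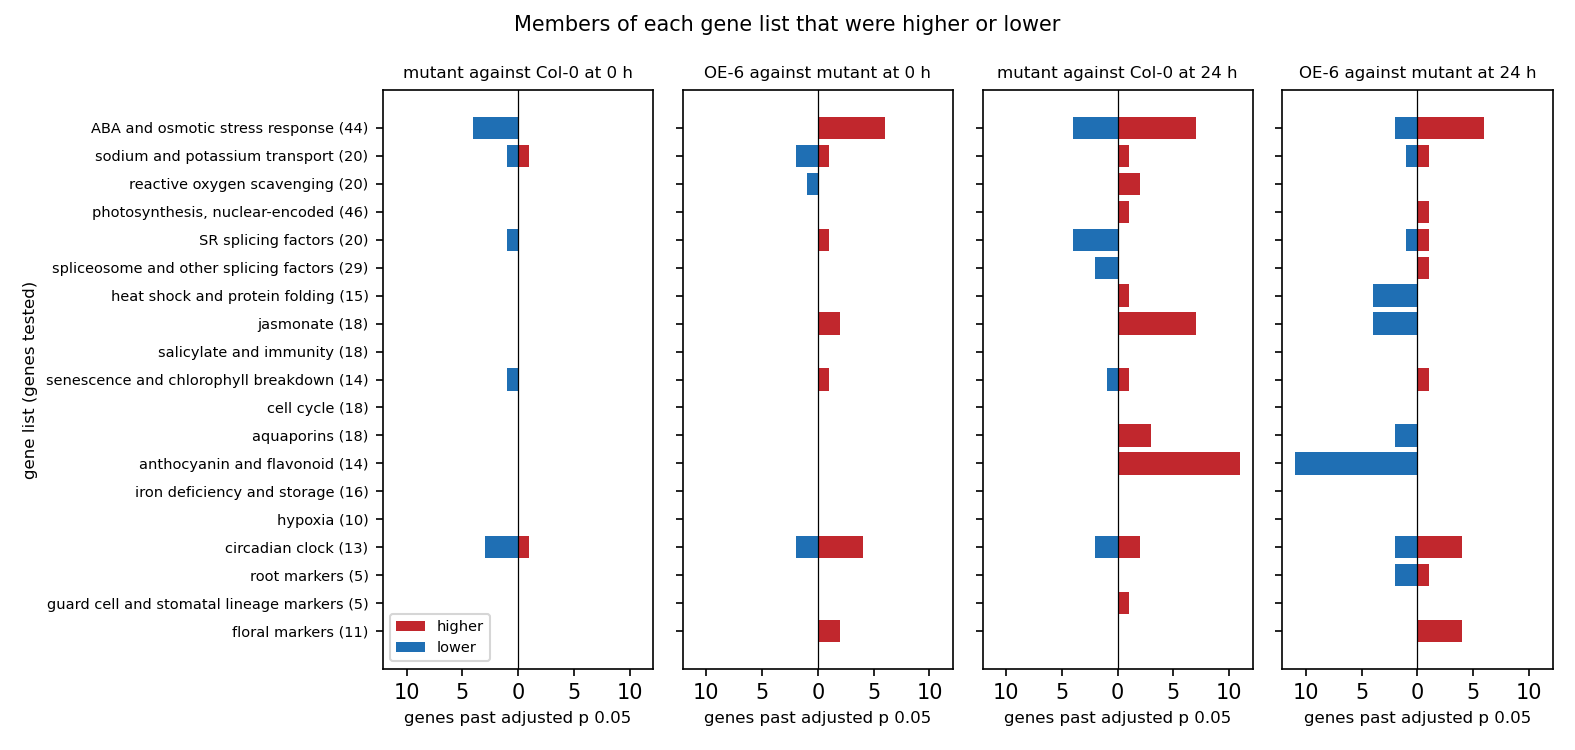
Number of genes in each of the 19 testable gene lists (y axis, with the number tested) that were higher (right of 0) or lower (left of 0) at an adjusted p under 0.05 (x axis), in the mutant against Col-0 and in OE-6 against the mutant. At 24 h, 11 of 14 anthocyanin genes were higher in the mutant and 11 were lower in OE-6.

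OE-6 and Col-0 were compared for what the transgene left different. At 0 h 3 genes differed. MAF5 was higher in OE-6 (30.7 ± 1.85 against 2.87 ± 1.37 CPM, 3.42 ± 0.26, adjusted p = 4.91e-05) and MRD1 lower (0.196 ± 0.148 against 37.4 ± 4.1 CPM, -7.55 ± 0.81, adjusted p = 0.00304). HEI10 was also lower (1.79 ± 0.512 against 8.43 ± 0.251 CPM), and is named after its values were seen because its mean is under 5 CPM. At 24 h MAF5 was the only gene called by edgeR (34.5 ± 6.75 against 1.49 ± 0.143 CPM, 4.53 ± 0.24, adjusted p = 2.54e-07). The floral list had a median of 1.71 at 0 h and 1.76 at 24 h with no member past the threshold, against 5 and 7 at an unadjusted p under 0.05 and 0 called by DESeq2 at either time (0 and 2 adjusted over the list alone). Camera gave adjusted p = 3.28e-14 and 9.65e-06, and adjusted p = 0.1 and adjusted p = 0.655 with an estimated correlation. Jasmonate genes at 0 h had a median of 0.40 (adjusted p = 4.57e-06, and adjusted p = 0.363 with an estimated correlation). Cell cycle genes at 24 h had one of -0.38 (adjusted p = 1.58e-07, and adjusted p = 0.655 with an estimated correlation). Neither list had a member past the threshold (0 and 2 adjusted over the list alone). Camera also called 6 lists at 0 h at an adjusted p of 0.0133 to 0.023, namely root markers (median -0.30), anthocyanin (0.57), other splicing factors (-0.08), iron (0.62), reactive oxygen scavenging (-0.13) and ABA (median -0.003 but mean 0.164), for which the smallest was adjusted p = 0.213 with an estimated correlation. At 24 h it called jasmonate (0.23), ABA (0.12) and senescence (0.17) at 0.0272 to 0.0349, with adjusted p = 0.655 the smallest with an estimated correlation. Over all 19 lists (354 genes) edgeR called 0 at either time, with 15 and 31 at an unadjusted p under 0.05 and 1 and 0 called by DESeq2. Among all genes, unadjusted p under 0.05 held for 436 genes at 0 h and 1693 at 24 h, and DESeq2 called 24 and 45. At 0 h the count was 6 without Col-0 0 h replicate 1 and 5 without OE-6 0 h replicate 3, and 18 with the groups compared alone. At 24 h it was 5 without OE-6 24 h replicate 1 and 85 without replicate 3.

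**Figure D3:**
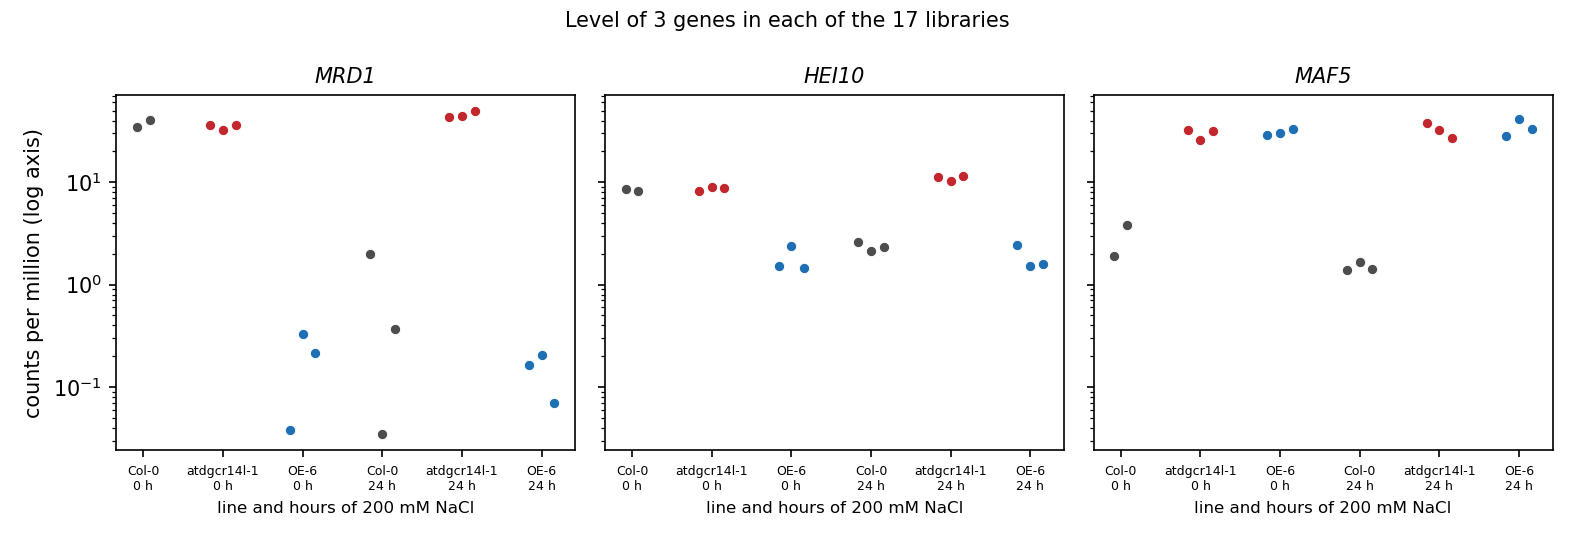
CPM on a log axis (y axis) of MRD1, HEI10 and MAF5 in each library (points) by line and hours of NaCl (x axis). MRD1 averages 37.4 in Col-0 at 0 h and 0.798 at 24 h, stays at 34.9 and 45.9 in the mutant and at 0.196 and 0.147 in OE-6, while MAF5 averages 29.8 or more in both atdgcr14l-1 and OE-6 and 2.87 or less in Col-0.

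The interaction of line and time tests whether the lines differed in their response to salt. For the mutant minus Col-0 only HEI10 passed (2.2 ± 0.28, adjusted p = 0.0262). Its level went from 8.43 ± 0.251 to 2.36 ± 0.255 CPM in Col-0 and from 8.63 ± 0.433 to 11.1 ± 0.626 in the mutant, with the caution on its overlap with MRD1. For OE-6 minus the mutant IGMT5 passed, an indole glucosinolate methyltransferase on chromosome 1 (28822186 to 28823727; -2.01 ± 0.26, adjusted p = 0.0175). IGMT5 went from 16.2 ± 2.26 to 220 ± 32.6 CPM in the mutant, from 31.8 ± 7.46 to 107 ± 8.3 in OE-6 and from 28.8 ± 0.987 to 117 ± 29.2 in Col-0. AT3G28290 on chromosome 3 (10547441 to 10549401; -1.86 ± 0.23, adjusted p = 0.0175) went from 25.9 ± 1.64 to 65.6 ± 4.86 CPM in the mutant, from 61.6 ± 15.4 to 43 ± 8.74 in OE-6 and from 50.3 ± 5.18 to 47.9 ± 3.9 in Col-0. It carries the same symbol, AT14A, as its neighbour AT3G28300, which was at 23.4 ± 1.75 and 56.3 ± 3.47 CPM in the mutant, so the 2 may share reads, and AT3G28300 itself was not called (-2.56 ± 1.29, adjusted p = 0.55).

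Among the lists, the log2 change with salt in the mutant minus that in Col-0 was positive by camera for jasmonate (median 0.94, camera adjusted p = 1.37e-10), anthocyanin (1.06, 8.84e-06), ABA (0.36, 6.79e-05), reactive oxygen scavenging (0.37, 0.021) and aquaporins (0.15, 0.0304) and negative for the cell cycle (-0.26, 0.0133). The median change of cell cycle genes was -1.19 in Col-0 and -1.45 in the mutant, and that of aquaporins -0.40 and 0.07. With an estimated correlation the 6 lists were at adjusted p = 0.396, adjusted p = 0.535, adjusted p = 0.791, adjusted p = 0.535, adjusted p = 0.791 and adjusted p = 0.892. No list member passed over all genes in edgeR, against 40 of 354 at an unadjusted p under 0.05 and 5 called by DESeq2, and adjusted over the list alone 5 jasmonate, 2 ABA and 1 anthocyanin genes did. For OE-6 minus the mutant the jasmonate median was -1.14 (camera adjusted p = 7.44e-13, and adjusted p = 0.247 with an estimated correlation; 11 lower adjusted over the list alone). The anthocyanin median was -1.33 (2.43e-09, and adjusted p = 0.27 with an estimated correlation; 5 lower adjusted over the list alone). Camera also called ABA (-0.36, 0.00024), heat shock (-1.27, 0.0266), salicylate (0.30, 0.0266) and aquaporins (-0.21, 0.0378), each at adjusted p = 0.642 with an estimated correlation. Over the 354 genes of all lists edgeR called 0, against 50 at an unadjusted p under 0.05 and 13 called by DESeq2.

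These 1 and 2 genes compare with 1900 and 2080 at an unadjusted p under 0.05 and with 122 and 236 called by DESeq2. The self-test recovered 39.6% and 42% of simulated 2-fold interactions. HEI10 was lost without Col-0 0 h replicates 1 or 2, atdgcr14l-1 0 h replicates 1, 2 or 3, Col-0 24 h replicates 2 or 3 or atdgcr14l-1 24 h replicate 1 (highest adjusted p 0.172). IGMT5 was lost without atdgcr14l-1 0 h replicates 1 or 3, OE-6 0 h replicate 1 or atdgcr14l-1 24 h replicate 1, and AT3G28290 without the same mutant libraries (highest adjusted p 0.0992 for each). Counts over left-out libraries ran from 0 to 14 for the mutant minus Col-0 (14 without atdgcr14l-1 24 h replicate 2, 4 without Col-0 24 h replicate 1, 3 without Col-0 0 h replicate 1 and 2 without atdgcr14l-1 24 h replicate 3). For OE-6 minus the mutant they ran from 0 to 68 (68 without atdgcr14l-1 24 h replicate 2, 63 and 60 without OE-6 24 h replicates 1 and 3, 7 without atdgcr14l-1 24 h replicate 3, 4 without OE-6 24 h replicate 2 and 1 without OE-6 0 h replicate 1).

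Because the series title concerns pre-mRNA splicing, genes with introns were compared with intronless genes. In the mutant against Col-0 the median change was -0.001 for 18060 genes with introns and -0.041 for 3086 intronless genes at 0 h, and 0.006 and -0.125 at 24 h. Camera on the intronless genes gave p = 0.0548 at 0 h and p = 0.000645 at 24 h in limma, and p = 0.0539 and p = 0.00297 with an estimated correlation. Against the mutant, intronless genes had higher medians in OE-6, of 0.092 against 0.004 at 0 h and 0.104 against -0.033 at 24 h. Camera in limma gave p = 0.00197 and p = 0.000509 for these, and p = 0.00533 and p = 0.00239 with an estimated correlation. OE-6 against Col-0 had medians of 0.03 for intronless genes and -0.005 for genes with introns at 0 h, and 0.008 and 0.003 at 24 h. For the intronless genes there camera in limma gave p = 0.0307 and p = 0.915, and p = 0.0335 and p = 0.905 with an estimated correlation. The difference between the 2 classes in the mutant, 0.040 at 0 h, was 0 with no filter on low counts and 0.017 without Col-0 0 h replicate 2. At 24 h it was 0.131, and 0.075 with no filter.

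The share of genes called higher in the mutant was larger among genes with many exons, a breakdown chosen after seeing the data. At 24 h 3.24% of single-exon genes and 23.2% of the 1259 genes with over 15 exons were higher in the mutant, while the shares lower were 8.17% and 2.07%. At 0 h the shares higher were 0.259% and 5.56%. In OE-6 against the mutant the shares lower were 0.745% and 12.8% at 0 h. At 24 h 81 of 3086 single-exon genes and 229 of the 1259 with over 15 exons were lower. For the genes with over 15 exons camera gave p = 4.03e-13 in the mutant at 24 h and p = 4.72e-07 at 0 h in limma, and p = 0.149 and p = 0.307 with an estimated correlation. In OE-6 against the mutant camera in limma gave p = 1.86e-08 at 24 h and p = 9.18e-19 at 0 h, and p = 0.257 and p = 0.0864 with an estimated correlation. The median change of the genes with over 15 exons was 0.085 at 0 h and 0.189 at 24 h in the mutant against Col-0. In OE-6 against Col-0 it was -0.084 at 0 h, of a size like that in the mutant, and 0.049 at 24 h. Camera in limma gave p = 1.05e-11 and p = 0.00667 for these, and p = 0.176 and p = 0.575 with an estimated correlation. A score per library, the median log2 deviation of genes with introns minus that of intronless genes, was 0.066 or more in the 3 mutant libraries at 24 h and 0.000 or less in the other 6. The 2-sided exact permutation p was 0.0119, the smallest that 84 arrangements allow (0.0238 after Benjamini-Hochberg adjustment over 4 such tests). At 0 h it was 0.030 or more in the mutant and 0.001 or less in the other 5 libraries (exact p = 0.0179 over 56 arrangements, 0.0239 adjusted). What the reads were aligned to is not given in the sources used here, and the aligner named does not split reads across introns, which could bear on how genes with many exons were counted.

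**Figure D4:**
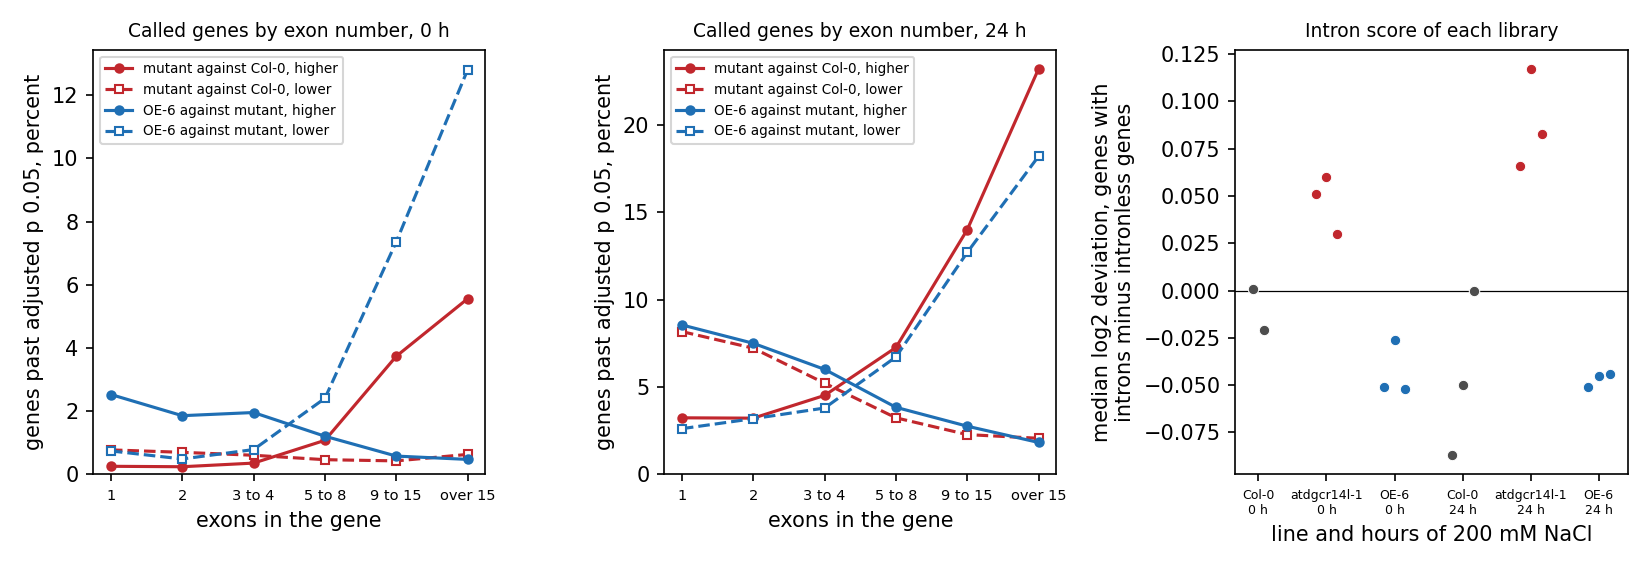
Left and centre: percent of genes at an adjusted p under 0.05 (y axis) by number of exons (x axis), higher or lower in the mutant against Col-0 and in OE-6 against the mutant, at 0 h and 24 h. Right: the intron score of each library (points, log2 units) by line and hours of NaCl, where the mutant libraries lie at 0.030 or above and all others at 0.001 or below.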

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

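The tests on MRD1 and HEI10 were chosen after the result was seen, while the interaction tests and the splits of the samples were not. The difference in salt response between atdgcr14l-1 and Col-0 passed the threshold for 1 gene, HEI10 (log2 2.2), and the difference between OE-6 and the mutant for 2, IGMT5 (-2.01) and AT3G28290 (-1.86). The first count was 0 without Col-0 0 h replicate 2, Col-0 24 h replicate 3, atdgcr14l-1 24 h replicate 1 or any 1 of the atdgcr14l-1 0 h libraries, and the second was 0 without atdgcr14l-1 0 h replicates 1 or 3 or atdgcr14l-1 24 h replicate 1. Of 50 splits of the OE-6 and mutant libraries 4 gave as many genes as the real one, so chance cannot be excluded for those 2, and the highest other split gave 389. The libraries of these lines vary more at 24 h, and whether this gave that split so many more genes was not tested.

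For whole lists, camera called a difference in salt response between the mutant and Col-0 for ABA (median 0.36), reactive oxygen scavenging (0.37), jasmonate (0.94), cell cycle (-0.26), aquaporins (0.15) and anthocyanin (1.06). None of the 6 was called with a correlation estimated per list, and 2 lists were called without atdgcr14l-1 24 h replicate 3. Jasmonate had 5 members past the threshold adjusted over the list alone, ABA 2 and anthocyanin 1.

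HEI10 and MRD1, which overlap on opposite strands, were high in Col-0 at 0 h and in the mutant at both times, and low in Col-0 at 24 h and in OE-6 at both times. A fall caused by salt as such is argued against by the mutant, where the smaller of the 2 changes with salt was 0.358, a rise. A wrong label on the Col-0 0 h libraries is argued against by AtDGCR14L, whose lowest level there was 55.71 CPM, against at most 13.06 CPM in any mutant library. What stays open, and was not tested, is that seed stocks of 1 line may differ at this locus between the plants sampled at 0 h and at 24 h, or that the loss of AtDGCR14L prevents a response to salt that OE-6 shows without salt. The counts of HEI10 could also hold reads of MRD1.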

How the results depend on the processing

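The alternative that leaves out both libraries standing apart was chosen after the data were seen, as were the checks on pairing. No named gene and no AtDGCR14L or intron difference changed sign under any alternative. The balance of counts in some lists did. Thus ABA genes in the mutant against Col-0 at 24 h went from 7 higher and 4 lower to 4 and 15 without both libraries standing apart, and to 2 and 3 without atdgcr14l-1 24 h replicate 3. The salt response in Col-0 numbered 6848 to 8931 genes over the libraries left out. The Col-0 0 h group is left with 1 library when either is dropped, which is then assumed to vary like the other groups. Depth limits genes at or near the floor of 3 counts, for which only bounds are given. At this depth and group size, with the same spread per gene in all groups, the self-test recovered 20% of 1.5-fold changes for the mutant against Col-0 at 0 h. It recovered 2% of interactions of that size, and depth alone was not varied. Transcript usage, the highest transcript per gene, TPM and FPKM could not be run on values per gene. Except where a cause is named, the cause was not tested.

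With a correlation estimated per list, 0 lists were called in any comparison, against 9 for salt in Col-0, 1 and 2 for the mutant against Col-0 at 0 h and 24 h, 3 and 7 for OE-6 against the mutant, and 6 for the interaction of the mutant. With no filter on low counts the intron difference was 0 at 0 h and 0.075 at 24 h, and with the 5 CPM filter 0.057 at 0 h. With only the groups compared, counts were 2330 and 827 for the mutant against Col-0, 3185 and 7 for OE-6 against the mutant, 18 for OE-6 against Col-0 at 0 h, and 4 and 0 for the interactions of the mutant and OE-6. That model takes its spread, filter and scaling from those groups. In the model of all groups, RLE scaling, no filter on low counts and the 5 CPM filter moved no count of genes by over 1.5 times. The spread was not varied by itself. For the mutant against Col-0 or OE-6, the groups alone gave more genes at 0 h and fewer at 24 h. At 24 h the mutant and OE-6 libraries lay further apart. DESeq2 gave 917 for the mutant at 0 h, 1596 and 3926 for OE-6 against the mutant, 24 and 45 for OE-6 against Col-0, 122 and 236 for the interactions, and 790 and 2424 genes moved back in OE-6. Without both libraries standing apart, counts were 1155 for OE-6 against the mutant at 24 h (4 lists), 4 for OE-6 against Col-0 at 24 h, 6 (3 lists) and 12 for the interactions, and 909 moved back at 24 h.

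With the replicate number as a block (replicate block), OE-6 against Col-0 at 24 h gave 2 genes and the interaction of the mutant 0 (HEI10 2.16, adjusted p = 0.135 in edgeR), and no other count moved by over 1.5 times. Taken over all groups the numbers do not pair the samples: 40 correlations between samples of the same number ran from -0.162 to 0.324. Their median was 0.001, and 4 lay over 0.1. Between OE-6 at 0 h and at 24 h, however, replicates 1, 2 and 3 gave 0.324, 0.151 and 0.077, the first being the highest. Libraries of OE-6 with the same number may therefore share structure over time, which the main model does not take up.

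Leaving out 1 library gave these ranges: AtDGCR14L with salt in Col-0 0.326 to 0.43; mutant against Col-0 90 to 214 genes at 0 h and 1109 to 3736 at 24 h; its intron difference 0.017 to 0.048 and 0.102 to 0.156. OE-6 against the mutant ran from 462 to 642 and 1452 to 4140, OE-6 against Col-0 from 3 to 6 and 1 to 85, the interactions from 0 to 14 and 0 to 68, and genes moved back from 84 to 313 and 828 to 2513. Lists called ran from 1 to 3 and 2 to 5 for the mutant against Col-0 and from 2 to 7 for its interaction. Of 259 named gene results, 66 lost their call with only the groups compared, 3 with DESeq2, 11 with the replicate block, 9 with no filter, 1 with RLE and 0 without organelle genes or among the 245 left by the 5 CPM filter, and 32 of 112 without both libraries standing apart. Over single libraries left out, 227 of 1456 did.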

Other observations

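The breakdown by exon number, the score per library, the bounds on leaving out 1 library, the test of MAF5 in OE-6 and the balance of MAF2, MAF3 and MAF4 were chosen after the result was seen. FLC, measured beside MAF5, averaged 3.21 CPM in Col-0, 7.12 in the mutant and 1.97 in OE-6 at 0 h, and 6.81, 10.4 and 3.34 at 24 h.

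Of the genes with over 15 exons 23.2% at 24 h and 5.56% at 0 h were called higher in atdgcr14l-1 than in Col-0, and 229 and 161 of the 1259 lower in OE-6 than in the mutant, while camera on this set gave p = 0.149, 0.307, 0.257 and 0.0864 in this order with an estimated correlation. Gene length, GC content and expression level are argued against as the whole cause, since the rank correlation with exon number kept at least 0.762 of its size after adjusting for all 3 together. Any 1 library is argued against at 24 h, where the difference of medians was at least 0.102 over those left out, but stays open at 0 h, where it went from 0.040 to 0.017 without Col-0 0 h replicate 2 and was 0 with no filter on low counts. The score per library separated the 3 mutant libraries from the other 6 at 24 h (2-sided exact p = 0.0119), which is consistent with an effect of losing AtDGCR14L, as a hypothesis found and tested on the same data. The real split of the 24 h libraries gave a difference of 0.131 and the highest other 0.09 (1 of 10 splits as large, too few for a share under 0.05). Unspliced reads, the way an aligner that does not split reads counts long genes, and other differences between the lines stay open. At 0 h the rank correlation with exon number was -0.188 in OE-6 against Col-0 and 0.148 in the mutant against Col-0. After adjusting for length, GC content and level together these were -0.027 and 0.22.

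MAF5 was high in both atdgcr14l-1 and OE-6. OE-6 argues against loss of AtDGCR14L as the cause. There AtDGCR14L did not differ from Col-0 past the threshold, and MAF5 exceeded the mutant level by at least 0.044 (log2). For reads shared in the MAF cluster, the 4 genes in the mutant summed to at least 1.37 times Col-0, between bounds set beforehand. The balance added later argues against sharing as the whole cause. From Col-0 to the mutant MAF2, MAF3 and MAF4 together changed by -2.0 CPM (0 h) and -5.2 (24 h), MAF5 by 26.9 and 30.8. MAF2 fell (46.7 to 39.3, 43.4 to 33.9). MAF4 rose (2.37 to 6.51, 1.3 to 4.93), also in OE-6 (5.73, 3.55). A difference at or near MAF5 in the mutant line may explain its rise and was not tested.

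The number of genes changed was compared with that in all other splits of the same libraries, which are too few (10) for a share under 0.05 in each 3 against 3 comparison. The real split and the highest other gave 12336 and 0 for salt in the mutant, 11759 and 0 for salt in OE-6, and 2633 and 0 for the mutant against Col-0 at 24 h. They gave 972 and 2 for OE-6 against the mutant at 0 h and 2546 and 365 at 24 h, and in each of these 5 only the real split was as large (1). For OE-6 against Col-0 at 24 h they gave 1 and 26, with 2 splits as large. For genes that moved back in OE-6 at 24 h they gave 1553 and 15 over 40 splits, 1 of them as large. That comparison decides nothing on the reversal, since 36 of the 39 other splits called no gene in at least 1 of the comparisons and could share none. Of camera calls, for the mutant at 24 h 2 lists stood against a highest other of 8 (10 of 10 as large). The numbers were 3 against 7 for OE-6 against the mutant at 0 h (8 of 10) and 7 against 10 at 24 h (3 of 10).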
